A study of Mus musculus with 2 samples.

How the data were processed

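Total RNA-seq was available for the adrenal glands of 2 female B6CASTF1/J mice aged 4 days. Per the labels, the libraries came from 300 ng of total RNA, were stranded and depleted of ribosomal RNA, and carried an ERCC spike-in mix. The protocols linked in the labels are those of a Norgen tissue RNA kit and an NEB directional library kit. Samples were grouped by tissue, age, sex and strain, which gave 1 group with 2 biological replicates, so no comparison between conditions and no paired analysis was possible. Which label text is right about the animal behind replicate 2 is not given in the sources used here.

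Per the file headers, each gene table gave an expected count, TPM, a posterior mean TPM and FPKM for 81881 sequences, of which 55536 were annotated genes, 96 were spike-ins or controls and 26248 carried a bare number as identifier. The authors' notes name the assembly mm10 and the annotation M21 and say that these tables were made from alignments to the transcriptome. The aligner, the quantifier and their versions are not given in the sources used here; the column names are those that RSEM writes. A deposited transcript table of the same kind gave expected counts and TPM per transcript. A second deposited transcript table, made from the read files per the authors' notes, gave estimated counts and TPM for 141864 sequences, with the column names that kallisto writes. It was summed to genes and is called the second quantification. The deposited TPM summed to the same total in each table, and the deposited FPKM was proportional to it. The effective length was 99 bases below the length in the first quantification, and 330 and 331 bases below it in the second, for replicates 1 and 2.

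The expected counts summed to 31838341 for replicate 1 and 32931868 for replicate 2, and the estimated counts of the second quantification to 32074016 and 32964074. At this depth a count of 0 allows a share of up to 9.42e-06% in replicate 1 and 9.11e-06% in replicate 2, which is 3 counts of the total. Intervals are 95% exact (Clopper-Pearson) binomial intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

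Genes were matched by identifier to the GENCODE M21 annotation, and all 55536 matched. Symbols of 29 gene lists and 12 gene pairs, fixed before the data were examined, were looked up there. The lists held 273 distinct symbols, of which 1, Ahsp, had no gene of that symbol, and some genes stood in more than 1 list, such as Scarb1, Nr5a1, Shh, Wnt4, Rspo3, Gli1 and Dlk1. The lists covered the zona fasciculata, zona glomerulosa, fetal cortex, adrenocortical development, cholesterol, chromaffin cells, neuroblasts, Schwann cells, capsule and fibroblasts, endothelium, smooth muscle, macrophages, lymphocytes, blood, kidney, adipose tissue, liver, pancreas, ovary, skeletal muscle, proliferation, immediate early genes, heat shock, the circadian clock, imprinted genes, X-linked and Y-linked genes, non-polyadenylated RNA and mitochondrially encoded proteins. Named genes followed a rule fixed at the same time. It took the 4 highest members of each list and every member of the 4 adrenal cell lists at 10 TPM or more. It also took members differing 2-fold at a mean count of 100, both genes of each pair, the 15 most abundant nuclear protein-coding genes, and the 10 genes furthest toward each animal. Of the genes it took, the text gives the main ones, and 1 of the pairs is not reported.

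Levels were deposited TPM, as mean and SD over 2 animals. A gene was detected at 1 TPM or more in both animals. Differences between the animals were log2 ratios of replicate 2 over replicate 1 from expected counts scaled by TMM, with a prior of 0.5 counts; genes at 0 in 1 animal were given a bound at 3 counts. The TMM factors were 1.01 and 0.988. Genes with a mean count of at least 100 were called when the ratio reached 2-fold, a rule of size and not a test. An exact conditional binomial test, two-sided and adjusted by Benjamini-Hochberg at 0.05, asked per gene whether the 2 libraries differed by more than sampling. The biological coefficient of variation was the square root of the common dispersion from an intercept-only fit in edgeR. For each list with at least 3 members at a mean count of at least 20, the median log2 ratio was placed among 10000 random lists of the same size, drawn from the 200 genes nearest to each member in expression. Log2 ratios of pairs used a pseudocount of 0.01 TPM, and the correlation a pseudocount of 1. Leading transcript shares were taken for genes with at least 5 TPM in both animals.

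Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. The steps were checked on simulated data. With the measured spread, 86% of genes changed by a log2 of 1.5 and 98% of those changed by 3 were called in the right direction, and 2.03% of unchanged genes were called. Of 200 random lists of 10 genes, 7.5% lay outside the central 95%, as did 100% of lists shifted by 1. A simulated coefficient of variation of 0.202 was recovered as 0.200. With no spread beyond counting, 0.0739% of unchanged genes passed the sampling test, and with the measured spread 69.4% did.

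Alternatives were other scalings (RLE size factors, spike-ins, deposited TPM), other count and TPM filters, other pseudocounts, posterior mean TPM, FPKM rescaled to the total of TPM, TPM rescaled over nuclear protein-coding genes, other dispersion estimates, the second quantification, and each animal alone. After the data were seen, values without the genes of the fixed lists for pancreas, kidney, skeletal muscle and liver, and of 4 further lists for these organs, were added. The sequences with a bare number as identifier were left out of the gene analyses because no table used here names them, and signal tracks were not used because they were not among the processed tables. The genes Gm26917 and Gm42418, which are known to collect ribosomal reads, were kept and took 5.42 ± 0.173% of counts (SD, n = 2).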

Results

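Total RNA was sequenced from the adrenal glands of 2 female mice aged 4 days. The animals were B6CASTF1/J, hybrids of a laboratory strain and a wild-derived strain, and formed 1 group of 2 biological replicates. The labels state no purpose and name no other condition, so the values describe which genes the newborn gland expressed, at which level, and how far the animals differed. The gene tables held 31838341 expected counts for replicate 1 and 32931868 for replicate 2. Levels are given in TPM, each gene's share of the library after division by its effective length, as mean ± SD over the 2 animals (n = 2), and positions are those of the mouse build mm10. The label texts conflict on the identity of replicate 2: its library text carries the animal number of replicate 1, its tissue text carries another number, and both samples share a donor record. The libraries are called animals here because their replicate numbers and tissue records differ. With 2 animals, the smallest p an exact two-sided sign-permutation test can give is 0.5, so no difference in this text is a test between conditions.

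The genes that turn cholesterol into corticosterone were among the most abundant nuclear protein-coding transcripts of both glands. Hsd3b1, which converts pregnenolone to progesterone, reached 2392 ± 252 TPM (SD, n = 2) and ranked 2 among nuclear protein-coding genes, behind the translation elongation factor gene Eef1a1 at 2843 ± 7.39 TPM (SD, n = 2). Cyp21a1, the hydroxylase acting on progesterone, stood at 1467 ± 70.8 TPM, and Cyp11a1, the side-chain cleavage enzyme that makes pregnenolone, stood at 868 ± 62.5 TPM (SD, n = 2). Star, which carries cholesterol into the mitochondrion, measured 816 ± 23.9 TPM, and Cyp11b1, the last enzyme of corticosterone synthesis, 598 ± 18.6 TPM (SD, n = 2). All 12 members of the list for glucocorticoid synthesis and the zona fasciculata, the glucocorticoid-making layer, exceeded 1 TPM in both animals, and their sum was 7268 ± 424 TPM (SD, n = 2). Fdx1 and Fdxr, which pass electrons to the mitochondrial steroid hydroxylases, measured 301 ± 4.81 and 227 ± 3.28 TPM (SD, n = 2). Scarb1, the receptor for high-density lipoprotein, measured 208 ± 0.82 TPM, and the steroidogenic transcription factor gene Nr5a1 157 ± 4.54 TPM (SD, n = 2). The corticotropin receptor gene Mc2r and its accessory protein gene Mrap were nearly level with each other, at 78.0 ± 3.61 and 77.6 ± 0.438 TPM (SD, n = 2). In the second quantification Mrap was higher, at 181 and 179 TPM in replicates 1 and 2, against 121 and 126 TPM for Mc2r. Akr1b7, an aldo-keto reductase gene induced by corticotropin, measured 78.3 ± 11.6 TPM (SD, n = 2). Of the 12 genes, 11 were higher in replicate 2 by TMM scaling, 10 by deposited TPM and 8 by spike-in scaling, and the median log2 ratio of 0.10 lay at percentile 94.7 of random lists matched on expression, inside their central 95%.

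These steroidogenic genes were identified by the following records. Hsd3b1 (ENSMUSG00000027871.16) lies on the minus strand of chromosome 3 from 98852194 to 98859794, and Cyp21a1 (ENSMUSG00000024365.9) on the minus strand of chromosome 17 from 34801348 to 34804561. Cyp11a1 (ENSMUSG00000032323.13) lies on the plus strand of chromosome 9 from 58006411 to 58027023, and Star (ENSMUSG00000031574.8) on the plus strand of chromosome 8 from 25806555 to 25815982. Cyp11b1 (ENSMUSG00000075604.5) and Cyp11b2 (ENSMUSG00000022589.7) are neighbours on the minus strand of chromosome 15, from 74834125 to 74841643 and from 74851010 to 74856318. Akr1c18 (ENSMUSG00000021214.14) lies on the minus strand of chromosome 13 from 4132615 to 4150654.

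Genes of the zona glomerulosa, the outer layer that makes aldosterone, had a lower sum than those of the fasciculata list. The fasciculata list includes general steroid synthesis genes, such as Star, Cyp11a1 and Cyp21a1, so the sums do not compare the layers. All 12 exceeded 1 TPM in both animals and summed to 431 ± 31 TPM (SD, n = 2). The highest was Dab2, an endocytic adaptor gene, at 167 ± 12.3 TPM, followed by the aldosterone synthase gene Cyp11b2 at 82.1 ± 24.8 TPM and the angiotensin II receptor gene Agtr1a at 55.3 ± 1.87 TPM (SD, n = 2). The signalling genes Wnt4 and Shh measured 28.0 ± 4.23 and 11.4 ± 2.10 TPM, the calcium channel gene Cacna1h 23.6 ± 0.424 TPM, and the potassium channel gene Kcnk9 22.8 ± 1.40 TPM (SD, n = 2). Hsd3b6, the paralog of Hsd3b1, measured 16.6 ± 0.120 TPM, and Vsnl1, a calcium sensor gene, 13.1 ± 1.02 TPM (SD, n = 2). Between the animals, 6 members were higher in each, or 4 in replicate 2 and 8 in replicate 1 by spike-in scaling, and the list median lay at percentile 40.1 of random lists. Cyp11b2 had a log2 ratio of replicate 2 over replicate 1 of -0.59 (95% counting interval -0.66 to -0.53), against 0.10 (0.08 to 0.11) for Cyp11b1. In the second quantification these ratios were -0.48 and 0.12.

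Akr1c18, a progesterone-inactivating enzyme gene used as an X-zone marker, was the highest gene of the fetal cortex list at 87.8 ± 4.47 TPM (SD, n = 2). The thyroid hormone receptor gene Thrb measured 16.2 ± 0.262 TPM, and the sum over the 4 members was 105 ± 4.87 TPM (SD, n = 2). Pik3c2g and Cyp17a1, the hydroxylase and lyase gene needed for cortisol and androgens, were near the detection floor at 0.495 ± 0.0919 and 0.365 ± 0.0495 TPM (SD, n = 2). Cyp17a1 rested on 21 counts in replicate 1 and 16 in replicate 2. The median log2 ratio of the 3 members with enough counts was -0.06, at percentile 29.2 of random lists. It was -0.17 with no filter on low counts.

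Fixed pairs of genes set these levels against each other within each animal. Cyp11b1 exceeded Cyp11b2 by a log2 ratio of 2.90 ± 0.49 (SD, n = 2), at 2.55 in replicate 1 and 3.24 in replicate 2. Hsd3b1 exceeded Hsd3b6 by 7.16 ± 0.14 and Cyp21a1 exceeded Cyp17a1 by 11.94 ± 0.26 on the log2 scale (SD, n = 2). Cyp11a1 exceeded Akr1c18 by 3.30 ± 0.18, and Mc2r exceeded the angiotensin receptor gene Agtr1b, itself at 3.51 ± 0.212 TPM, by 4.47 ± 0.15 on the log2 scale (SD, n = 2). Each of these 5 ratios was larger than its spread between the animals. Hsd3b1 and Hsd3b6 share sequence, as Cyp21a1 does with a pseudogene, so reads can be divided between such paralogs. Cyp11b1 and Cyp11b2 had fractional expected counts, so some of their reads may also have been divided.

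**Figure D1:**
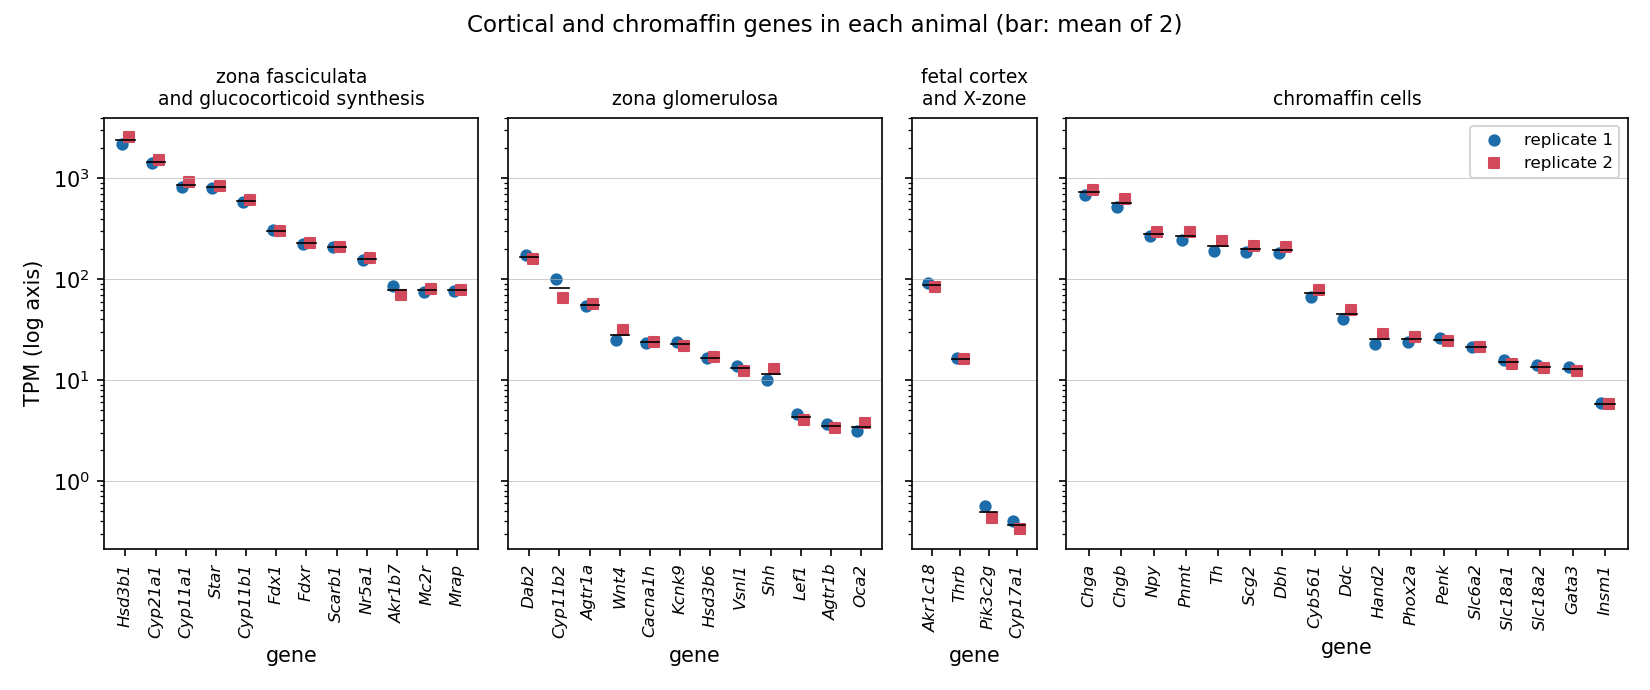
Level of each gene in TPM (vertical axis, logarithmic) for 4 gene lists (panels), with 17 of the 18 chromaffin genes shown, with 1 circle for replicate 1, 1 square for replicate 2 and a bar at their mean (n = 2). Hsd3b1 is highest at 2392 TPM, and Cyp11b2 shows a wide gap between the animals, with 99.6 TPM in replicate 1 and 64.6 TPM in replicate 2.

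Genes of adrenocortical development and of cholesterol supply were read in full. All 13 members of the development and signalling list exceeded 1 TPM in both animals, with a sum of 842 ± 69.4 TPM (SD, n = 2). The imprinted gene Dlk1 led with 391 ± 60.8 TPM, and the transcriptional cofactor gene Cited2 measured 51.5 ± 5.25 TPM (SD, n = 2). Gata6 measured 37.6 ± 4.84 TPM and the hedgehog receptor gene Ptch1 29.8 ± 0.318 TPM (SD, n = 2). The development list was higher in replicate 2, with 10 of 13 members on that side, or 9 by spike-in scaling and by deposited TPM, and a median log2 ratio of 0.10, at percentile 98.1 of random lists. In the second quantification it lay at percentile 96.8, inside the central 95%. All 17 genes of cholesterol synthesis, uptake and storage exceeded 1 TPM in both animals and summed to 781 ± 12.1 TPM (SD, n = 2). Soat1, which esterifies cholesterol for storage, stood at 207 ± 24 TPM, Hmgcs1 at 75.1 ± 1.58 TPM and Dhcr7 at 67.5 ± 0.735 TPM (SD, n = 2). Of the 17 genes, 12 were higher in replicate 1, or 15 by spike-in scaling and 13 by deposited TPM, and the median log2 ratio of -0.08 lay at percentile 0.62 of random lists. Their summed TPM was instead slightly higher in replicate 2, at 773 TPM in replicate 1 and 790 TPM in replicate 2. Among the 5 members higher in replicate 2 by TMM scaling, Soat1 had a log2 ratio of 0.19 and the lipase gene Lipe 0.18.

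Genes of the adrenal medulla were abundant in both animals. All 18 genes of the chromaffin cell list, the cells that make catecholamines, exceeded 1 TPM in both animals and summed to 2736 ± 280 TPM (SD, n = 2). The granule protein genes Chga and Chgb measured 730 ± 66.0 and 572 ± 70.2 TPM, Npy, a neuropeptide gene, 280 ± 20.2 TPM (SD, n = 2), and Scg2 186 TPM in replicate 1 and 214 TPM in replicate 2. Of the catecholamine enzymes, Pnmt, which makes adrenaline, stood at 268 ± 33.0 TPM, Th, the rate-limiting enzyme, at 213 ± 34.3 TPM, Dbh at 196 ± 17.3 TPM and Ddc at 45.1 ± 6.42 TPM (SD, n = 2). The vesicular monoamine transporter genes Slc18a1 and Slc18a2 measured 15.2 ± 0.827 and 13.6 ± 0.714 TPM, and the noradrenaline transporter gene Slc6a2 21.2 ± 0.134 TPM (SD, n = 2). Among sympathoadrenal transcription factor genes, Hand2 measured 25.8 ± 4.33, Phox2a 25.4 ± 2.11 and Gata3 12.8 ± 0.764 TPM (SD, n = 2). The enkephalin gene Penk measured 25.2 ± 1.41 TPM and the cytochrome gene Cyb561 of the granule membrane 73.1 ± 8.22 TPM (SD, n = 2). Of the 18 genes, 15 were higher in replicate 2, or 13 by spike-in scaling and by deposited TPM and 17 in the second quantification, with a median log2 ratio of 0.19, above the central 95% of random lists (-0.05 to 0.09).

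Th (ENSMUSG00000000214.11) lies on the minus strand of chromosome 7 from 142892752 to 142931128, and Pnmt (ENSMUSG00000038216.7) on the plus strand of chromosome 11 from 98386450 to 98388181. The log2 ratio of Th to Pnmt was -0.34 ± 0.06 (SD, n = 2), so Pnmt was the higher of the pair in both animals. Slc18a1 exceeded Slc18a2 by 0.16 ± 0.003 and Chga exceeded Chgb by 0.35 ± 0.05 on the log2 scale (SD, n = 2). Cyp11b1, a cortical gene, exceeded the medullary gene Th by 1.63 on the log2 scale in replicate 1 and by 1.37 in replicate 2. In the second quantification the ratio of Slc18a1 to Slc18a2 was 0.45 and that of Chga to Chgb 0.13, each further from the value given than the spread between the animals.

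Neuronal and glial genes were read at lower levels. The 8 genes of neuroblasts and neurons summed to 104 ± 2.13 TPM, led by Stmn2 at 48.8 ± 1.39 TPM and the peripheral neurofilament gene Prph at 23.1 ± 1.87 TPM (SD, n = 2). The neuropeptide gene Cartpt measured 14.3 ± 3.37 TPM (SD, n = 2). The 9 genes of Schwann cells and their precursors summed to 52.7 ± 6.63 TPM, with the myelin gene Mbp at 10.5 ± 0.24 TPM and the precursor gene Sox10 at 3.46 ± 0.0990 TPM (SD, n = 2). Both lists lay inside the central 95% of random lists, at percentiles 51.2 and 79.9.

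Connective tissue, vessels and immune cells were also represented. The 13 genes of capsule and fibroblasts summed to 1396 ± 141 TPM, with the collagen genes Col3a1 at 399 ± 50.3, Col1a1 at 341 ± 33.4 and Col1a2 at 266 ± 20.7 TPM (SD, n = 2). This list was higher in replicate 2, with 8 of 13 members on that side under every scaling, a median log2 ratio of 0.21 and percentile 99.98. The other 5 members were Wt1, Tcf21, Pdgfra, Nr2f2 and Gli1, with log2 ratios of -0.98, -0.33, -0.20, -0.08 and -0.05. The 11 endothelial genes summed to 409 ± 11.2 TPM, led by Egfl7 at 97.2 ± 11.7 TPM and the fenestral diaphragm gene Plvap at 62.3 ± 2.30 TPM (SD, n = 2). The 6 genes of smooth muscle and pericytes summed to 83.7 ± 0.0778 TPM, with Acta2 at 25.9 ± 0.368 TPM (SD, n = 2). Neither list lay outside the central 95%, at percentiles 90.1 and 41.9. The 10 macrophage and myeloid genes summed to 127 ± 27.1 TPM, and all 10 were higher in replicate 2, except Cd163 by spike-in scaling, with a median log2 ratio of 0.37 above the central 95% (-0.12 to 0.13). Examples were the lysozyme gene Lyz2 at 27.5 ± 8.66 TPM and the complement genes C1qa, at 17.5 TPM in replicate 1 and 22.6 TPM in replicate 2, and C1qb, at 16.8 and 23.3 TPM. The skeletal muscle and liver lists were also higher in replicate 2, and genes of fibroblasts and macrophages do not tell cells of the gland from those of other tissue. The 8 lymphocyte genes summed to 1.91 ± 0.948 TPM (SD, n = 2) on 79 and 131 counts. None of them reached 1 TPM in both animals. Their median log2 ratio of 0.82 lay at percentile 97.9, but was 0.34 and inside the central 95% in the second quantification.

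The profiles of the animals were close for most genes. Of 55536 annotated genes, 14669 reached 1 TPM in both animals, 13067 of them protein-coding and 194 long intergenic non-coding, and 1389 reached it in 1 animal. Across 29246 genes above 0 in either animal, Pearson's r of log2(TPM + 1) was 0.980 and Spearman's rho 0.944, where genes are not independent replicates. The biological coefficient of variation from edgeR was 0.202 over 18462 genes. Among 13734 genes with a mean count of at least 100, the median absolute log2 ratio was 0.108, against 0.0443 from counting alone, and 12803 genes (93.2%) lay within 0.5. By an exact conditional binomial test per gene, 4469 (32.5%) differed by more than sampling allows, so the tables do not hold 1 set of counts deposited a second time. In data simulated with a coefficient of variation of 0.202 for every gene, 69.4% of unchanged genes did so, so this coefficient overstates the spread of a typical gene. The housekeeping genes Rpl41 at 1271 ± 14.1, Actb at 1188 ± 27.9, Tpt1 at 1181 ± 40.4 and Rps27 at 902 ± 15.5 TPM were among the most abundant, with the alcohol dehydrogenase gene Adh1 at 1675 ± 89.5 TPM and the matrix gene Sparc at 865 ± 61.2 TPM (SD, n = 2).

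Genes typical of other organs made up the largest differences between the animals. The 5 pancreas genes summed to 3293 TPM in replicate 1 and to 0.51 TPM in replicate 2, on 77815 and 19 counts. The chymotrypsinogen gene Ctrb1 (ENSMUSG00000031957.6, chromosome 8, 111686519 to 111691010) had 51016 counts, 2127 TPM, in replicate 1 and 6 counts in replicate 2, a log2 ratio of -12.95 (95% counting interval -14.51 to -11.95). The elastase gene Cela2a and the insulin gene Ins2 had no count in replicate 2 and were at least 4188-fold and at least 1486-fold higher in replicate 1, against a floor of 3 counts per library. The carboxypeptidase gene Cpa1 was 834-fold higher in replicate 1. The list median was -12.95, or -10.54 with the genes at 0 set to 3 counts. Amy2a5, Amy2a1 and the trypsinogen genes Prss2 and Try5 were at least 3527-fold, 1431-fold, 2364-fold and 1999-fold higher in replicate 1, while Amy2a2, Amy2a3 and Amy2a4, which share reads, were listed with the same 4047 counts each against 0.

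Kidney genes were also higher in replicate 1. All 10 differed at least 2-fold, and they summed to 109 TPM in replicate 1 and 11.7 TPM in replicate 2, with a median log2 ratio of -3.26. The phosphate transporter gene Slc34a1 had a log2 ratio of -3.29 (95% counting interval -3.46 to -3.12), the endocytic receptor gene Lrp2 -2.84 (-2.94 to -2.74), and the salt transporter gene Slc12a1 -3.44 (-3.73 to -3.17). Kap, with 165 and 2 counts, had a log2 ratio of -6.06 (-9.44 to -4.51). Genes of skeletal muscle and liver were higher in replicate 2. All 5 muscle genes differed at least 2-fold and summed to 267 and 1694 TPM, with a median log2 ratio of 2.65. The actin gene Acta1 had a log2 ratio of 2.74 (2.70 to 2.79) and the creatine kinase gene Ckm 2.82 (2.73 to 2.91). All 7 liver genes differed at least 2-fold and summed to 141 and 602 TPM, with a median of 2.16. The albumin gene Alb had a log2 ratio of 2.19 (2.14 to 2.24), and the alpha-fetoprotein gene Afp 2.15 (2.06 to 2.25). These 4 lists lay outside the central 95% of random lists, and no member changed direction under any scaling or in the second quantification. In contrast, the 5 ovary genes summed to 0.875 ± 0.163 TPM (SD, n = 2), and none had a mean count of 20.

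**Figure D2:**
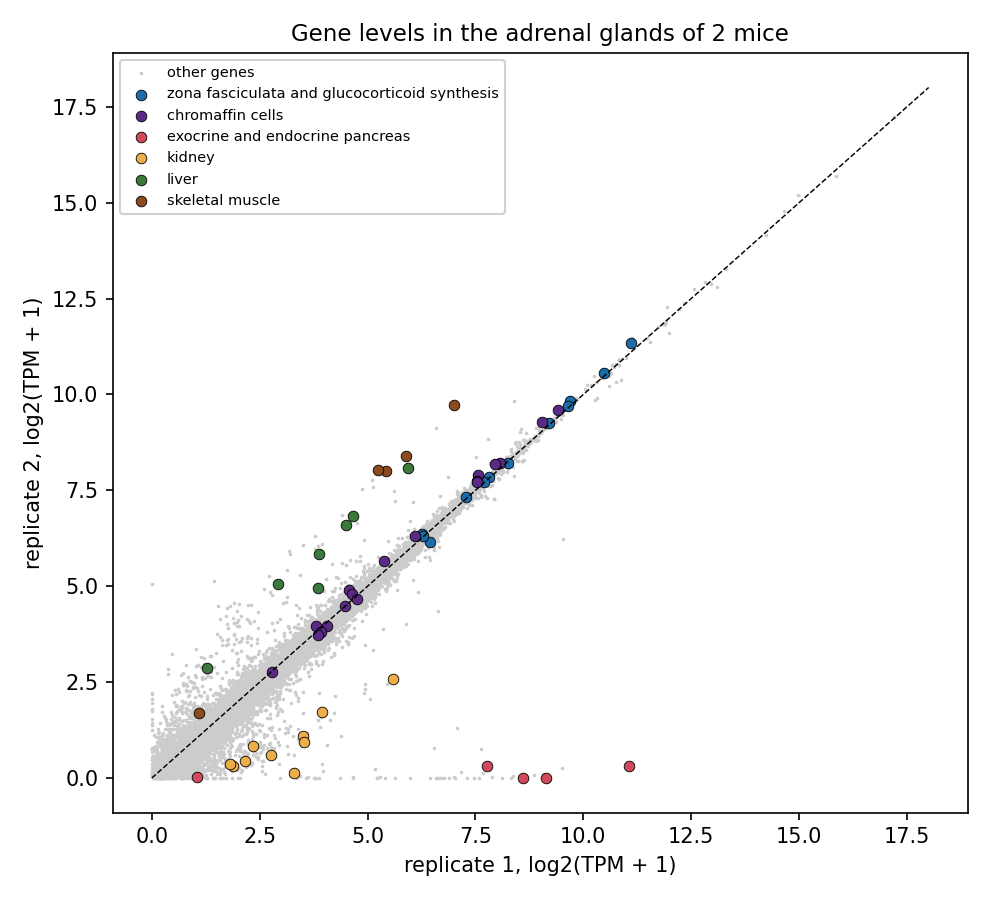
Level of every gene in replicate 1 (horizontal axis) against replicate 2 (vertical axis), both as log2(TPM + 1), with 1 point per gene, members of 6 lists in colour and a dashed line of equality. Fasciculata and chromaffin genes lie along the line, the 5 pancreas genes and the 10 kidney genes lie on the replicate 1 side, and the 5 muscle and 7 liver genes lie on the replicate 2 side.

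In all, 440 of the 13734 genes (3.20%) differed at least 2-fold, 236 of them higher in replicate 1 and 204 in replicate 2. Without the genes of the fixed and further lists for pancreas, kidney, muscle and liver, 361 remained, 195 and 166 by direction. These lists do not hold every gene of those organs. The 361 still include the amylase genes Amy2a1, Amy2a2, Amy2a3 and Amy2a4, and muscle or heart genes such as Myl2 and Myh7. At 10-fold, 68 genes were higher in replicate 1 and 5 in replicate 2. Beside the pancreas genes, the 10 genes furthest toward replicate 2 included 9 genes expressed in muscle or heart, such as Myl2, with a log2 ratio of 4.26 (95% counting interval 3.73 to 4.90), Myh7, with 3.57 (3.39 to 3.77), Myl3, Myh6, Mb, Art1, Myoz2, Smtnl1 and Sln. The other, Fam177a, had 0 and 209 counts, at least 69.0-fold, but stood at 7.82 and 6.47 TPM in the second quantification. The count of 2-fold genes depended on the filter, with 994 genes at a minimum mean count of 20 and 86 at a minimum 10 times the one used.

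Blood, fat, and stress and growth genes differed by smaller amounts. The erythroid list summed to 4551 ± 1027 TPM (SD, n = 2) over 9 matched genes, and all 8 with enough counts were higher in replicate 1 under every scaling, with a median log2 ratio of -0.50 below the central 95% of random lists (-0.09 to 0.14). Its adult globin genes Hba-a1 at 1607 ± 391, Hbb-bs at 1497 ± 318 and Hba-a2 at 1084 ± 219 TPM were among the 15 most abundant nuclear protein-coding genes (SD, n = 2). Reads can be divided between the paralogous globin genes. The embryonic globin gene Hbb-y had no count in either animal, so Hbb-bs exceeded it at least 7209-fold at a floor of 3 counts. The 7 adipose genes summed to 717 ± 61.9 TPM, with Fabp4 at 350 ± 45.0, Plin1 at 135 ± 8.93 and the brown fat gene Ucp1 at 124 ± 10.2 TPM (SD, n = 2). Of these 7, 6 were higher in replicate 2 under every scaling, and the median log2 ratio was 0.31, at percentile 99.99. All 11 immediate early genes were higher in replicate 2, except Jun by spike-in scaling and by deposited TPM, with a sum of 136 ± 34.7 TPM (SD, n = 2) and a median log2 ratio of 0.63, above the central 95% (-0.13 to 0.12). Nr4a1, an orphan receptor gene induced by corticotropin, had a log2 ratio of 1.23 (95% counting interval 1.14 to 1.31), Junb 1.02 (0.86 to 1.18) and Jun 0.03 (-0.06 to 0.12). The median was 0.31 for members with a mean count of at least 100. All 7 heat shock genes were higher in replicate 2 under every scaling, with a sum of 723 ± 61.9 TPM (SD, n = 2), a median of 0.20 and percentile 99.2, as for the chaperone gene Hspa8 at 540 ± 51.5 TPM (SD, n = 2).

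Imprinted genes were highly expressed and leaned toward replicate 2. The 17 genes summed to 4857 ± 870 TPM (SD, n = 2), 15 were higher in replicate 2, or 14 by spike-in scaling and 16 by deposited TPM, and the median log2 ratio of 0.19 lay at percentile 99.98. Gnas, which encodes the stimulatory G protein, measured 1147 ± 85.6 TPM, Meg3 777 ± 14.8 TPM, H19 622 ± 404 TPM, and the growth inhibitor gene Cdkn1c 527 ± 46.2 TPM (SD, n = 2). H19 and the growth factor gene Igf2, which newborn muscle and liver also express, differed at least 2-fold, with log2 ratios of 1.47 (95% counting interval 1.44 to 1.49) and 1.01 (0.98 to 1.04). Within each animal Igf2 was below H19, with a log2 ratio of -0.81 ± 0.27 (SD, n = 2). H19 (ENSMUSG00000000031.16) lies on chromosome 7 from 142575529 to 142578143 and Igf2 (ENSMUSG00000048583.16) from 142650766 to 142666816, both on the minus strand.

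**Figure D3:**
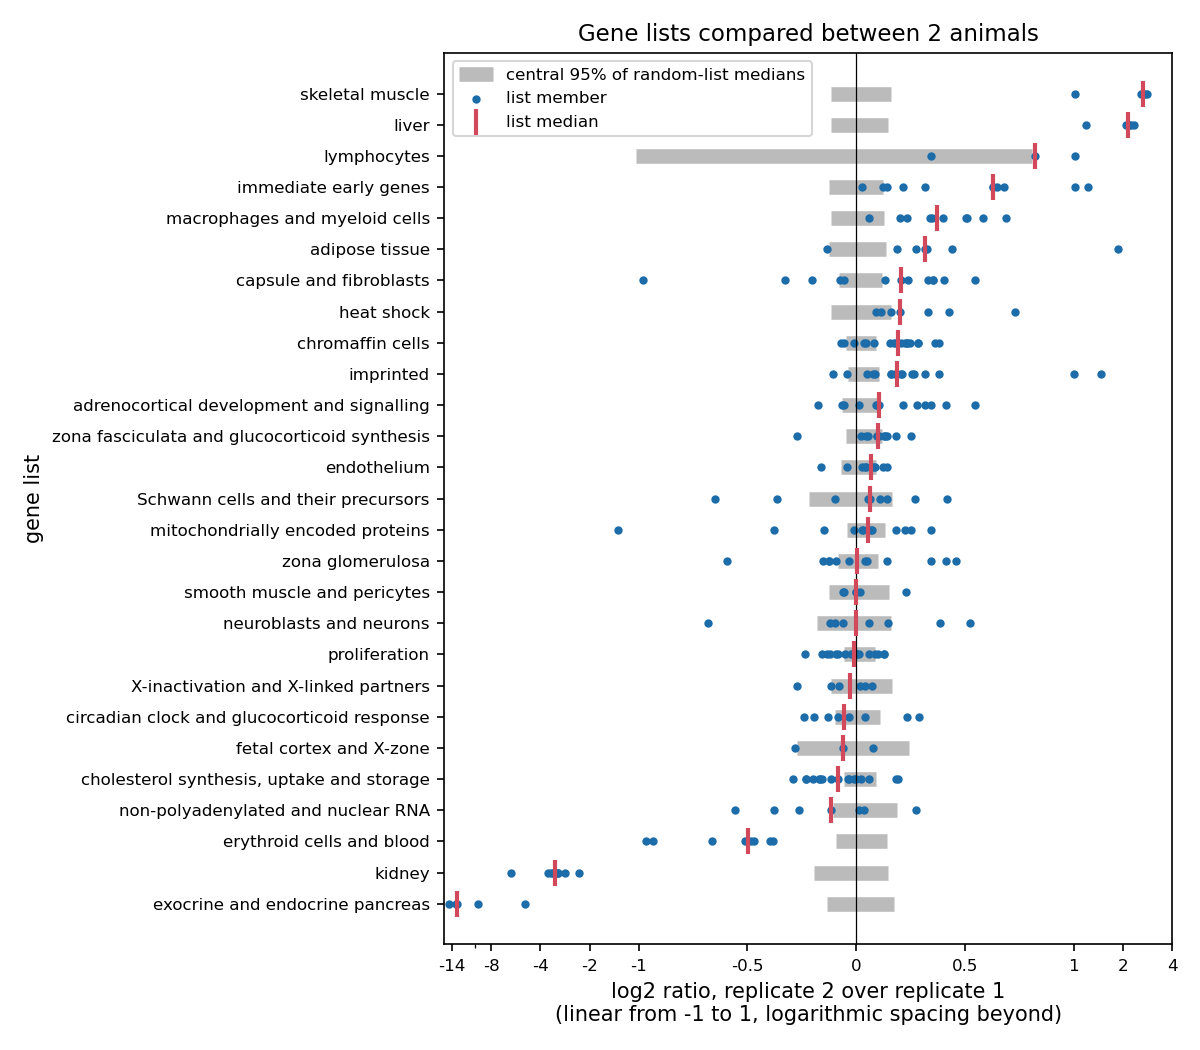
Log2 ratio of replicate 2 over replicate 1 (horizontal axis, linear from -1 to 1 and logarithmic beyond) for the 27 tested gene lists (vertical axis), with 1 point per member, a bar at the list median and a grey band for the central 95% of medians of 10000 random lists. The pancreas, kidney, liver and skeletal muscle lists lie furthest from 0, with medians of -12.95, -3.26, 2.16 and 2.65, where genes at 0 take a prior of 0.5 counts.

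Genes of dividing cells, of the clock and of the sex chromosomes were read next. The 18 proliferation genes summed to 487 ± 6.45 TPM, with the replication clamp gene Pcna at 57.1 ± 0.735, the helicase genes Mcm6 at 41.0 ± 2.15 and Mcm7 at 40.7 ± 1.13, and Top2a at 40.7 ± 0.198 TPM (SD, n = 2). The 8 genes of the circadian clock and glucocorticoid response summed to 201 ± 3.61 TPM, with Per1 at 38.6 ± 4.38, Nr1d1 at 34.0 ± 4.62 and the glucocorticoid target gene Fkbp5 at 33.2 ± 1.51 TPM (SD, n = 2). The 6 genes of X-inactivation and X-linked partners summed to 365 ± 24.8 TPM, with Xist, the RNA that silences an X chromosome, at 114 ± 16.8 TPM (SD, n = 2). These 3 lists lay inside the central 95% of random lists, at percentiles 27.1, 8.96 and 20.4. Within the last, Xist had a log2 ratio of -0.27 (95% counting interval -0.29 to -0.25). The 4 Y-linked genes held 1 count in replicate 1 and 6 counts in replicate 2, too few to place among random lists, and in the second quantification they summed to 1.92 and 2.70 TPM.

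Of the 27 tested lists, 16 lay outside the central 95% of random lists, 5 toward replicate 1 and 11 toward replicate 2, where 5% of 27, or 1.35, would be so by chance, although 7.5% of simulated random lists lay outside and some lists share members. Without the genes of the pancreas, kidney, muscle and liver lists, 12 of 23 lists did. The random lists ignore that genes of a cell type vary together. Scaling to the spike-ins moves every gene and every random list alike, so it cannot change these percentiles, and by that shared shift alone the medians of the glomerulosa, Schwann cell, endothelium and mitochondrial lists went from positive to negative.

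RNA classes other than nuclear messenger RNA held a large part of the libraries. Nuclear protein-coding genes took 71.2 ± 0.364% of counts, the mitochondrial ribosomal RNAs 7.22 ± 0.669%, mitochondrial protein-coding genes 2.53 ± 0.0998%, and long intergenic RNAs 7.28 ± 0.375% (SD, n = 2). Gm26917 and Gm42418, which are known to collect ribosomal reads, took 5.42 ± 0.173% of counts (SD, n = 2). They were not taken out of these shares, so most of the long intergenic share may be ribosomal reads. The share of mitochondrial protein-coding genes, and their TPM sum below, leave out reads given to Gm28661 and Gm28437. These nuclear copies of mt-Co2 and mt-Co3 had 130268 and 82958 counts in replicate 1, and 145378 and 107315 in replicate 2. Both mitochondrial values may therefore be too low. The signal recognition particle RNA genes Rn7s1 and Rn7s2 took 5.91 ± 0.0737% of counts but 30.4 ± 0.386% of TPM, because TPM divides by a short effective length (SD, n = 2). The 6 symbols of the list of non-polyadenylated and nuclear RNA matched 7 genes, which summed to 81520 ± 6049 TPM, with Rn7sk at 56047 ± 4139, Rpph1 at 9995 ± 113 and Malat1 at 3571 ± 639 TPM (SD, n = 2). Their median log2 ratio of -0.12 lay at percentile 1.33 of random lists, and was -0.35 in the second quantification, which assigned almost no reads to the short ones. The 13 mitochondrially encoded protein genes summed to 28669 ± 676 TPM, with the oxidase gene mt-Co1 at 6457 ± 599 and mt-Nd1 at 3675 ± 5.63 TPM (SD, n = 2). They lay at percentile 64.4, and at percentile 97.51, just outside the central 95%, in the second quantification with a median of 0.16. Their member mt-Co2 had a log2 ratio of -1.33 (95% counting interval -1.48 to -1.18) but of 0.90 in the second quantification.

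For 30 genes of the fasciculata, glomerulosa, fetal cortex and chromaffin lists with more than 1 transcript, the leading transcript held 79.9 ± 1.22% of the gene's TPM on average (SD, n = 2). It held at least 90% in 10 of them, such as Cyp11a1 at 97.4 ± 0.236% and Th at 99.98 ± 0.0262%, and under 50% in 2, Dab2 at 33.8 ± 2.81% and Thrb at 33.5 ± 0.235% (SD, n = 2). The second quantification named the same leading transcript for 24 of the 30 and another for Hsd3b1, Nr5a1, Cacna1h, Thrb, Ddc and Slc6a2. The shares it gave lay more than 1 SD from those of the first in 23 of the 30. For Th the leading transcript held 75.4% there.

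Spike-in RNAs took 0.900% of counts in replicate 1 (95% Clopper-Pearson interval 0.897 to 0.904%) and 0.923% in replicate 2 (0.919 to 0.926%), a mean of 0.912 ± 0.0156% (SD, n = 2). Each library started from 300 ng of RNA per the labels. In each animal 71 of the 96 spike-in sequences were read, and the 29 with a mean count of at least 100 had a median log2 ratio of 0.08, from -0.31 to 0.21. Levels in TPM depend on the quantification: the fasciculata list summed to 13220 TPM and the chromaffin list to 5119 TPM in the second quantification, which leaves short RNAs out of the total.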

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

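No test in this part was chosen after the result was seen. The sequences that carry a bare number as identifier, which no gene analysis used, held 14.7 expected counts in replicate 1, above the 3 counts that a count of 0 allows, and 2 counts in replicate 2. Of 26248 such sequences, with a median length of 73 bases, 6 were above 0 in replicate 1 and 2 in replicate 2. They took 4.61e-05% and 6.07e-06% of the counts. No technical or biological explanation was tested for them.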

How the results depend on the processing

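The coefficient of variation from the second quantification, the values without genes of the fixed and further pancreas, kidney, skeletal muscle and liver lists, and the spike-in share of each animal alone were chosen after the data were seen. The log2 ratios of 2 of the 440 genes differing 2-fold changed direction, both in the second quantification alone: mt-Co2 from -1.33 to 0.90, weighed in the next part, and Fam177a from a bound toward replicate 2 to -0.21, where the cause was not tested. There, 2 others had no count. Of the lists inside the central 95%, spike-in scaling turned the medians of 4 from positive to negative by its shared shift, and those for neuroblasts, smooth muscle and X-linked genes, near 0, changed sign under RLE size factors, a mean count of at least 100 or the second quantification. No pair ratio changed sign under any alternative. RLE size factors and spike-in scaling move all genes alike, so the percentiles of the lists stayed the same by construction and these scalings test nothing there. Of the 16 lists outside the central 95%, the second quantification lost the development and lymphocyte lists and gained the mitochondrial list, and no filter gained the Y-linked list. At a mean count of at least 100 the lymphocyte list had no member and was not tested, and the other 15 stayed outside. Of the 440 genes differing 2-fold, 429 were called again under spike-in scaling, 427 with deposited TPM and 413 in the second quantification, all in the same direction. Each animal alone gave means, sums and shares within 1 SD by construction and, since detection required both animals, more detected genes (15143 and 15584 against 14669), and leaving out an animal was impossible for results between animals. FPKM rescaled to the total of TPM is the same quantity as TPM and tests nothing. The pair of Hbb-bs and Hbb-y gave no value under any alternative, and other splits of the samples did not apply to 1 group of 2. For the following values the cause was not tested, except where stated.

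The correlation was 0.967 with a pseudocount of 0.1, and 0.955 (Pearson) and 0.961 (Spearman) over genes with at least 1 TPM in either animal. The median gene-wise dispersion of DESeq2 gave a coefficient of variation of 0.0001, the lower bound the tool allows. The number of genes differing 2-fold was 994, 86 and 7168 at a minimum mean count of 20, at 10 times the minimum used, and with no filter, which change the genes tested. Rescaling over nuclear protein-coding genes gave sums of 19963, 1184, 288 and 7516 TPM for the fasciculata, glomerulosa, fetal cortex and chromaffin lists by construction. In the second quantification these sums were 13220, 888, 184 and 5119 TPM, the leading transcript share was 67.4%, and log2 ratios were 11.60 for Cyp21a1 to Cyp17a1, 4.32 for Mc2r to Agtr1b, 0.45 for Slc18a1 to Slc18a2, 0.13 for Chga to Chgb and 1.12 for Cyp11b1 to Th. A pseudocount of 1 gave 10.07, 4.13 and 0.15 for the pairs led by Cyp21a1, Mc2r and Slc18a1, and posterior mean TPM gave 11.13 and 0.19 for those led by Cyp21a1 and Slc18a1. The values of 0.15 and 0.19 lay inside the counting intervals of that ratio in both animals. The spike-in share was 1.23% of TPM. Depth limits Cyp17a1, Pik3c2g, and the lymphocyte, ovary and Y-linked genes, whose counts were few.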

Other observations

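The gene groups of the next paragraph, and the tests of a wrong label, of a shared sequencing pool, of library scaling and of counting error, were chosen only after the results were seen.

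Levels were also taken for 2 further gene groups and for a group of slow-twitch and cardiac muscle genes. No enrichment was tested, and the libraries also held genes of other organs. All 8 slow-twitch and cardiac muscle genes, some of them named above, were higher in replicate 2, with a median log2 ratio of 3.27 (range 2.27 to 4.26). Of 12 genes for secretory granule proteins, processing enzymes and neuropeptides, 10 exceeded 1 TPM in both animals, with a sum of 438 ± 10.1 TPM (SD, n = 2). The carboxypeptidase gene Cpe measured 188 ± 3.90 TPM, the amidating enzyme gene Pam 109 ± 3.09 TPM and Resp18 51.7 ± 3.70 TPM (SD, n = 2). Of the 12, 10 had a log2 ratio within 0.5 of 0, whereas the convertase gene Pcsk2 had -0.94 (95% counting interval -1.13 to -0.75) and Vip, on 16 and 25 counts, 0.61 (-0.33 to 1.63). All 12 genes of steroid metabolism and nuclear receptors exceeded 1 TPM in both animals, with a sum of 243 ± 7.19 TPM (SD, n = 2). The electron carrier genes Cyb5a and Por measured 69.2 ± 1.93 and 61.6 ± 2.52 TPM, the prolactin receptor gene Prlr 52.8 ± 2.57 TPM and the glucocorticoid receptor gene Nr3c1 19.7 ± 0.877 TPM (SD, n = 2). Hsd11b2, which inactivates glucocorticoids, had a log2 ratio of -1.39 (-1.73 to -1.08), and Hsd11b1, which regenerates them, 0.58 (0.21 to 0.96).

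Pancreas genes were read in replicate 1 and hardly in replicate 2. A wrong label that put another tissue in place of a gland is argued against by the fasciculata list, whose median log2 ratio was 0.10 where another tissue would lack these genes. That list cannot tell the gland of 1 animal from that of another, so it does not bear on the conflicting labels of replicate 2. Pancreatic tissue or its RNA in the replicate 1 sample is a candidate explanation: in a further list of 17 pancreas genes, 94.1% (16 genes) were at least 10-fold higher in replicate 1 with at least 100 counts there, 8 were at 0 in replicate 2, and the most abundant gene of the fixed list, Ctrb1, reached 2127 TPM, while Cela1 and Cpb1 of the further list still had 541 and 121 counts in replicate 2, and Cela1, with a log2 ratio of -2.38, was the exception to the 10-fold difference. Amy2a5, Prss2 and Try5 of the further list were already named above among the genes furthest toward replicate 1, so they are no separate check. Reads from a pancreas library in the same pool cannot be told apart from pancreatic tissue in the sample, since the make-up of the pool is unknown. Replicate 2 held 19 counts of the fixed list. No biological explanation was tested, because the design gives none.

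Kidney genes were higher in replicate 1, and muscle and liver genes in replicate 2. A difference in library scaling is argued against by the gap of 5.91 log2 units between the muscle and kidney medians, since scaling moves all lists alike. Other tissue carried along with the gland may account for the pattern: in further lists, 100% of members with enough counts (12 kidney, 15 muscle and 11 liver genes) differed at least 2-fold in the direction of the fixed list, and Acta1 reached 840 TPM and Alb 269 TPM in replicate 2. In the animal with the lower levels, muscle and liver genes were still read, at sums of 267 and 141 TPM. No biological difference between the animals was tested.

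The genes mt-Co2 and mt-Co3 differed in direction between the quantifications, with log2 ratios of -1.33 and -0.38 in the first and 0.90 and 0.37 in the second. For counting error, the second value of mt-Co2 lay 2.08 above the upper bound of the first interval. That interval cannot decide here, since it covers sampling between libraries and both quantifications come from the same libraries. Reads shared with nuclear copies may account for the differing directions: Gm28661 and Gm28437 on chromosome 1 hold 99.5% and 99.9% of the 31-base words of mt-Co2 and mt-Co3. With the copies added, the larger gap between the quantifications was 0.0531, at 0.13 against 0.19 for mt-Co2 and 0.21 against 0.24 for mt-Co3. For mt-Co2 this check decides little, because Gm28661 makes up nearly all of the sum. In the first quantification mt-Co2 had 1287 and 517 counts in replicates 1 and 2, against 130268 and 145378 for Gm28661. No biological explanation was tested.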
